A study of Solanum lycopersicum and Solanum pimpinellifolium with 9 samples.

How the data were processed

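The series measured transcripts of tomato by pyrosequencing of cDNA libraries. The samples were 7 tissues of Solanum lycopersicum cultivar MoneyMaker, the cultivated tomato, and 2 tissues of the accession LA0722 of Solanum pimpinellifolium, a wild red-fruited relative. Per the labels' protocols, plants were grown in a greenhouse under 16 h of light and 8 h of dark, cDNA was made with a PCR synthesis kit, and each library was run on the 454 Titanium system with a goal of at least 350000 reads of about 400 bp. Each of the 9 groups holds 1 library. No comparison therefore has a replicate check, and no test between groups was run.

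The deposited table gives RPKM values, that is reads scaled by the length of the gene model and by the reads of the library, which the authors computed for 34727 gene IDs in 9 columns with 2 decimals. Per the submitters' processing notes, HTSeq is among the tools; its version, the aligner, the genome build, the annotation and any filters are not given in the sources used here. Columns were matched to samples by name. The MoneyMaker column named for mature fruit does not say green. It was taken as mature green, the only sample whose labels say mature. The MoneyMaker column named for a berry with the number 10 was taken as the ripe fruit sample by elimination, because the other MoneyMaker fruit columns are named for mature fruit and for breaker. The deposited table lists IDs of the Solyc form with no gene names or products. The reference gene table used here, of 41476 genes, contained 0 of these IDs, so genes are given by ID only, at most 2 per direction in a comparison, and the tests planned on lists of named genes (such as ethylene, carotenoid and cell wall genes) and on markers of other cell types were not run. No coordinates are printed, because no genome of the authors' build was used here.

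Whole reads were recovered from the RPKM values. In a library the values of a gene are whole multiples of what 1 read is worth, so ratios of low values between libraries gave the relative depth, and the steps of each gene gave its reads and a whole-number length. All 23089 genes listed above 0 had a solution, and 100.0% of their 128956 values came within 0.05 of a whole read. Closeness to whole reads was required of every length accepted, so this figure is no check of the recovery. The products of length and total fixed both only up to a common factor. With lengths taken as multiples of 3, which is an inference, the totals came to between 211200 and 380304 reads per library. The recovered reads summed to 95.5% to 99.9% of those totals without having been fitted to them, so the values were taken as relative to reads assigned to genes and the lengths as coding lengths (median 1134 nt over genes listed in 7 or more libraries). The smallest read numbers that fit were used, so reads of a gene listed in few libraries can be a fraction of the true ones. In a test on simulated data over 22085 genes, 98.1% of read numbers were recovered exactly, 99.7% for genes listed in 5 or more libraries, and 100.0% were exact or too low. The simulation took the recovered reads and lengths as its truth, so genes already reduced to a fraction do not count as errors in it. Where lengths hold no untranslated parts, RPKM of genes of short coding length can be inflated by reads that reach into those parts. An equal inflation in both libraries leaves the ratio of a gene's RPKM unchanged. It can still change the difference after a fixed pseudocount and whether the gene reaches a fixed level, both given below.

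For each comparison the difference of log2(RPKM + 5) between the libraries was taken. The pseudocount of 5 RPKM was set from the read goal as about the worth of a pair of reads, and it makes the difference understate the fold of low genes. A gene counted as higher or lower when the difference reached 2 log2 units (4-fold) and the higher library had at least 25 RPKM. The words higher and lower below refer to this rule of size unless values are given. A gene was tissue-predominant when it met the same rule against the next highest of the 7 MoneyMaker libraries; for the organ count the 3 fruit libraries were represented by their highest value. Per comparison the genes named are the 2 with the largest difference in each direction. Comparisons, thresholds, the naming rule and the alternatives were fixed before the data were examined. The 4 organ sets, the contrast of ripe fruit with leaf within each species, the use of the ripening genes in LA0722 and the draws of counting error were chosen after seeing the data.

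An organ set holds the genes predominant in 1 of the 4 MoneyMaker libraries that are not fruit, against the other 3 of those libraries, so that no fruit or LA0722 library took part in choosing it. The median difference of a set in another comparison was set against 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries; the range given holds 95% of the lists. Folds of named genes come from recovered reads with the 95% exact (Clopper-Pearson) interval of the share of reads in the higher library. A gene listed at 0 was compared with a floor of 3 reads in that library, and the fold is then given as at least that large. Intervals and floors cover counting error only, and PCR reads without molecular identifiers are not independent molecules. To set the size of counting error, 100 draws were made in which both libraries of a comparison shared 1 expression rate per gene. In simulations of mature green against ripe fruit over 34727 genes, with 200 genes changed, the rule of size recovered 38.0% of 4-fold changes, 99.5% of 8-fold changes and 100.0% of 16-fold changes; the 8-fold figures were 98.5% for leaf between the species and 99.5% for ripe fruit between the species.

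Alternatives were pseudocounts of 1 and 20 RPKM, no minimum level or 100 RPKM, 3 other scalings of the libraries (median-ratio size factors over the 1110 genes at 25 RPKM or more in every library, upper quartile, and equal sums without the 10 most abundant genes of any library), a rule of size of 1 log2 unit, and only genes whose exact interval on recovered reads excluded no change. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9.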

Results

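RPKM values were compared between 9 libraries of tomato tissues. From MoneyMaker there were root, upper stem, fully expanded leaf, open flower without sepals, and fruit at the mature green, breaker (turning colour) and ripe (red) stages. From LA0722, the wild relative, there were fully expanded leaf and ripe fruit. The leaves were 2 to 3 weeks old in MoneyMaker and 2 to 4 weeks old in LA0722. The totals of reads assigned to genes that the values imply came to 337996 in root, 337067 in stem, 380304 in MoneyMaker leaf, 213741 in flower, 346942 in mature green, 214609 in breaker and 270465 in MoneyMaker ripe fruit, 300890 in LA0722 leaf and 211200 in LA0722 ripe fruit. The reads recovered gene by gene summed to slightly less, between 204210 in flower and 379524 in MoneyMaker leaf. At the implied totals 1 read on a coding length of 1 kb was worth 2.63 RPKM in MoneyMaker leaf and 4.74 RPKM in LA0722 ripe fruit, the libraries with the highest and the lowest implied total. Each value stands for 1 library, so differences between libraries could be set against counting error but not against the spread between plants.

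Root drew on the most genes and flower on the fewest. At 25 RPKM or more there were 7150 genes in root, 6803 in mature green fruit, 6609 in stem, 6003 in breaker fruit, 5808 in MoneyMaker ripe fruit, 5445 in LA0722 leaf, 5438 in LA0722 ripe fruit, 4770 in MoneyMaker leaf and 3478 in flower. The 10 most abundant genes took 7.6% of summed RPKM in root and 9.5% in stem, against 22.5% in MoneyMaker leaf, 22% in flower and 24.4% in LA0722 ripe fruit. Solyc07g049140 was the most abundant gene of all 4 fruit libraries. It stood at 35856 RPKM in mature green, 64802 in breaker and 103487 in ripe MoneyMaker fruit and at 153272 RPKM in LA0722 ripe fruit, where it alone took 11.1% of summed RPKM. Its inferred coding length was only 291 nt, so its RPKM can be inflated. By reads it held 9420 of the 210817 recovered in LA0722 ripe fruit. The same gene was listed at 0 in stem and in both leaf libraries. Solyc03g005760 led both leaf libraries, with 62008 RPKM in MoneyMaker and 35153 RPKM in LA0722, and also stem, with 16531 RPKM. Solyc01g066370 led flower with 82120 RPKM and was listed at 0 in root, stem, both leaves, mature green fruit and MoneyMaker ripe fruit. It stood at 65.2 RPKM (6 reads) in breaker fruit and 77.3 RPKM (7 reads) in LA0722 ripe fruit. These leading genes were picked after their values were seen. With every library thinned to 204210 reads, the number of genes expected above 0 was 16130 in root, 15084 in stem, 14788 in mature green, 13523 in breaker and 12458 in ripe MoneyMaker fruit, 13270 in MoneyMaker leaf, 12543 in LA0722 leaf, 12151 in LA0722 ripe fruit and 10948 in flower.

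Breaker and ripe fruit of MoneyMaker had the closest expression profiles. Library correlations were taken over all 34727 gene IDs, of which 11638 were listed at 0 in every library, so shared zeros enter each value. Across genes, which are not independent replicates, the Pearson correlation of log2(RPKM + 5) was 0.88 between breaker and ripe MoneyMaker fruit, the highest of the 36 library pairs, and 0.83 between mature green and breaker. Ripe fruit of MoneyMaker and LA0722 correlated at 0.83, and the leaves of the 2 species at 0.77. Stem correlated with leaf at 0.81, with mature green fruit at 0.80 and with root at 0.80. Flower stood apart from every other library, at 0.46 to 0.51.

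The first question was which genes mark each tissue of MoneyMaker. Flower had the largest number of genes predominant in a single library, 775, and they took 71.9% of its summed RPKM. Root had 563 such genes, with 14.3% of its RPKM, leaf had 305 with 44.4%, and stem had 100 with 3.4%. Mature green, breaker and ripe fruit had 120, 91 and 92, but with the 3 fruit stages taken as a single organ 822 genes were fruit-predominant. In root, Solyc03g020070 stood at 2478 RPKM (201 reads) and was listed at 0 in every other library, at least 66.8-fold above the stem floor, while Solyc04g007760 stood at 11579 RPKM, 486-fold above MoneyMaker leaf (95% exact interval 189 to 1784). In leaf, Solyc03g005780 stood at 8647 RPKM, 345-fold above the next library, mature green fruit (167 to 858), and Solyc03g123410 at 6123 RPKM, 162-fold above root (82.1 to 376). The flower genes Solyc10g075130 and Solyc09g007780 stood at 25524 and 24036 RPKM and were listed at 0 in the 6 other MoneyMaker libraries, at least 259-fold and 512-fold above the root floor. They held 491 and 971 reads on inferred coding lengths of only 90 and 189 nt, so their RPKM can be inflated. In fruit, Solyc10g017980 reached 33237 RPKM in the ripe MoneyMaker library and was listed at 0 in root, stem, leaf and flower, at least 719-fold above the root floor. Its inferred coding length was 192 nt. Solyc07g049140 was the other leading fruit gene, 3218-fold above flower, where it had 2 reads (891 to 26580). The 2 leading stem genes, Solyc07g061810 at 165 RPKM and Solyc07g045490 at 132 RPKM, rested on the smallest read numbers that fit, 4 and 2, too close to the floor of 3 reads to give a fold. At 1 kb that floor was worth 8.88 RPKM in root and 8.90 RPKM in stem, against 14.0 RPKM in flower and in breaker fruit. Folds above a shallower library listed at 0 are therefore smaller than those given against root or stem. The lead of flower over root turned with a rule of 1 log2 unit, which gave 979 flower- and 1044 root-predominant genes. The counts also depended on scaling: under median-ratio size factors, which multiply flower and leaf values upward, 1328 genes were flower-predominant, 630 leaf-predominant and 513 fruit-predominant, so that flower and leaf gained genes and fruit lost them.

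The organ sets, chosen without any fruit library, showed how transcripts typical of other organs behaved in ripening fruit. The leaf set of 447 genes took 3.10% of summed RPKM in mature green fruit, 1.92% in breaker fruit and 0.78% in ripe MoneyMaker fruit. From mature green to ripe, 112 of its 205 members at 25 RPKM or more were lower and 9 were higher, and their median log2 difference was -2.35, below the range of -0.55 to 0.0 that held 95% of the random lists. The stem set went the same way, with 46 of 78 members lower, 4 higher and a median of -2.66 (random lists -0.91 to 0.15), although its share of summed RPKM moved only from 4.23% to 3.46%. The root set moved upward between mature green and breaker, with 65 of 174 members higher, 40 lower and a median of 0.61 (random lists -0.80 to -0.22). The flower set had 36 of 160 members higher and 15 lower at that step, with a median of 0.41 (random lists -0.57 to -0.06), but 12 higher and 29 lower from breaker to ripe, with a median of -0.31 (random lists -0.21 to 0.35). That last median was -0.11 with upper-quartile scaling and -0.55 with median-ratio size factors. Over the whole span the flower set's median of -0.21 lay within the random range of -0.55 to 0.07 and turned to 0.50 with upper-quartile scaling. From breaker to ripe the leaf set had a median of -1.15, with 60 of 159 members lower and 9 higher, while the root set, with a median of 0.04, lay within its random range of -0.16 to 0.35 and was -0.56 with median-ratio size factors. From mature green to ripe the leaf, stem and root medians kept their sign under the 3 other scalings but varied in size: the leaf median was -1.43 with median-ratio size factors and the root median 1.57 with upper-quartile scaling. Other settings, which also redefined the sets, moved the leaf, stem and root medians too. With no minimum level, so that members at 0 in both libraries counted, they were -0.16, 0.0 and 0.0. With sets chosen by 1 log2 unit they were -1.04, -0.92 and 0.31. At a level of 100 RPKM the leaf and root medians grew to -3.44 and 1.76. The root median from mature green to breaker was 0.07 with sets chosen by 1 log2 unit, 1.70 with median-ratio size factors and 2.19 with upper-quartile scaling. With upper-quartile scaling the leaf set, redefined under it, had a median of -1.25 from mature green to ripe and only -0.04 from mature green to breaker.

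**Figure D1:**
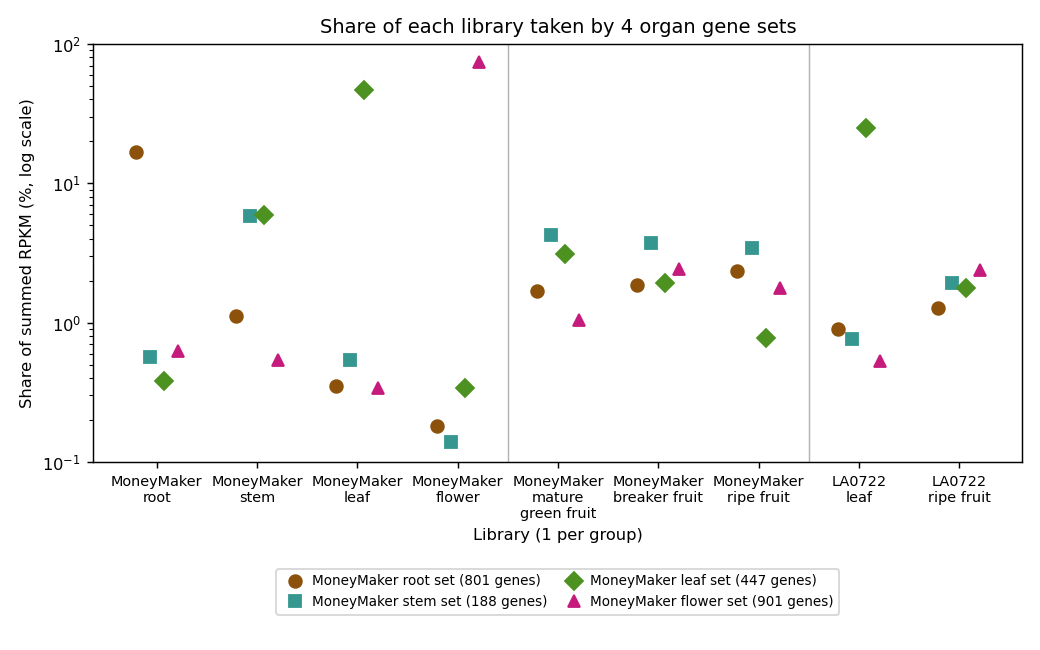
Share of summed RPKM (percent, log axis) that each of the 4 organ sets took in each of the 9 libraries, 1 point per set and library, with no error bars because each group has 1 library; vertical lines part MoneyMaker organs, MoneyMaker fruit and LA0722. The leaf set went from 3.10% to 0.78% over the MoneyMaker fruit stages and stood at 46.4% in MoneyMaker leaf and 24.8% in LA0722 leaf.

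The ripening series addressed which genes differ between mature green, breaker and ripe fruit. From mature green to breaker 689 genes were higher and 934 lower among 8098 compared, and from breaker to ripe 513 were higher and 619 lower among 7255. Over the whole span 689 were higher and 1228 lower among 8097. The 689 genes higher in breaker than in mature green fruit grew from 2.0% of summed RPKM in mature green to 22.9% in breaker and held 15% in ripe fruit; 283 of them were fruit-predominant and 1 was leaf-predominant. The 1228 genes lower in ripe than in mature green fruit shrank from 20.9% of summed RPKM to 5.7% in breaker and 1.2% in ripe fruit. Of these 1228 genes, 171 were fruit-predominant and 72 leaf-predominant, and 586 stood at 25 RPKM or more in MoneyMaker leaf. The share of all compared genes at that level in leaf was not computed. The shares of summed RPKM are taken in the libraries that chose the genes, except breaker in the second case and ripe in the first. Counting error alone gave means of 118.8 higher and 170.5 lower genes from mature green to breaker and 150.2 and 130.6 from breaker to ripe. Over the whole span the means were 95.9 and 115.8, and all these means lay below the counts observed.

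Solyc10g080210 showed the largest increase at the onset of ripening. It was listed at 0 in mature green fruit, stood at 7237 RPKM in breaker (2134 reads) and 12830 RPKM in ripe MoneyMaker fruit (4768 reads), at least 1150-fold and 2039-fold above the mature green floor, and was listed at 0 in root, stem, leaf and flower. Solyc03g082370 went from 10.7 RPKM, a single read, to 6368 RPKM in breaker (369 reads), a fold of 597 with an interval of 106 to 23625, and was also present in root at 1194 RPKM. Solyc08g005770 was listed at 0 in mature green fruit and reached 1466 RPKM in breaker and 3007 RPKM in ripe fruit, at least 462-fold above the floor. On the way down, Solyc00g265510 went from 2844 RPKM to 0 in breaker, at least 15.3-fold lower, and Solyc08g080490 from 2094 RPKM to 0, at least 65.2-fold lower. In mature green fruit Solyc00g265510 held 74 reads on an inferred coding length of only 75 nt. Solyc03g034220, at 34546 RPKM in MoneyMaker leaf, stood at 3010 RPKM in mature green and 1133 RPKM in breaker fruit and was listed at 0 in ripe fruit, at least 147-fold below mature green. Between breaker and ripe, Solyc02g090120 went from 0 to 1275 RPKM and Solyc07g054790 from 0 to 840 RPKM, at least 23.8-fold and 16.4-fold higher, and Solyc06g060840 dropped from 2508 to 9.13 RPKM, 275-fold with an interval of 48.8 to 10901.

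Few genes passed the rule at both steps in the same direction, but for genes lower in breaker the rule itself limited this number. Of the genes higher in breaker than in mature green fruit, 485 stayed within the rule of size from breaker to ripe, 15 were higher again and 189 were lower in ripe than in breaker fruit. Of the 934 genes lower in breaker, 22 were lower again, 145 were higher in ripe than in breaker fruit and 767 passed in neither direction. However, 517 of the 934 were listed at 0 in breaker fruit and could not be lower again. The 767 include genes below the minimum level in both breaker and ripe fruit, which were not compared at that step. The 767 therefore cannot be read as genes that stayed stable. A further 353 genes were higher and 408 lower only at the step from breaker to ripe. Draws with counting error only gave a mean of 49.3 genes that rose then fell and 63.9 that fell then rose (highest 72 and 84), because both steps use the same breaker library, and at most 1 gene in either direction at both steps. The balance of directions depended on scaling and on the rule. From mature green to breaker the majority also turned with a pseudocount of 20 RPKM (343 higher and 328 lower) and with a level of 100 RPKM (347 and 290), and from breaker to ripe with a rule of 1 log2 unit (1529 and 1478). Of the genes past the rule, 42.5% were higher from mature green to breaker as deposited and 55.1% with upper-quartile scaling, which shifts breaker by 0.26 log2 units against mature green, so the direction of the majority turned, as it did with median-ratio size factors (51.7%, 670 higher and 626 lower). From breaker to ripe 45.3% were higher as deposited and 30.9% with median-ratio size factors, a shift of -0.35, and over the whole span 35.9% and, with upper-quartile scaling and a shift of 0.33, 49.7%.

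**Figure D2:**
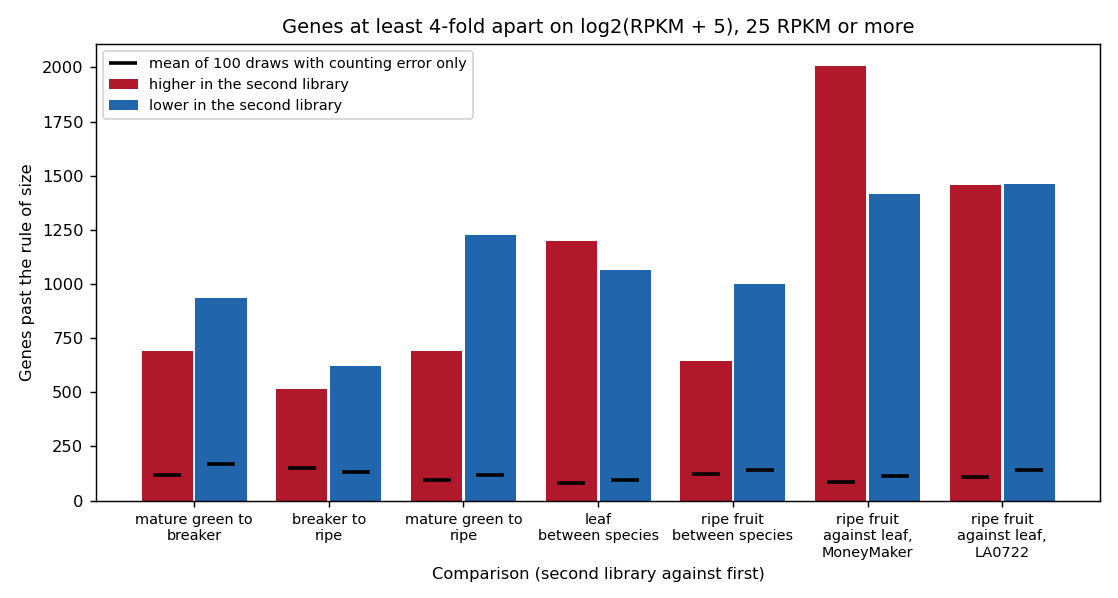
Number of genes past the rule of size in each comparison of 2 libraries (bars from 0), higher or lower in the second library, with black lines at the mean of 100 draws that hold counting error only. From mature green to ripe fruit 689 genes were higher and 1228 lower, against 95.9 and 115.8 from counting error.

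Leaf was compared between LA0722 and MoneyMaker. In LA0722 leaf 1197 genes were higher and 1063 lower among 7015 compared, against means of 80.5 and 95.6 from counting error alone. The MoneyMaker leaf set, which was chosen on the MoneyMaker library and therefore leans toward it, took 46.4% of summed RPKM in MoneyMaker leaf and 24.8% in LA0722 leaf, where 266 of its 447 members stood at 25 RPKM or more. Solyc02g084850 was listed at 0 in MoneyMaker leaf and stood at 1057 RPKM in LA0722 leaf, at least 52.7-fold higher, and Solyc06g051680 at 0 and 295 RPKM, at least 13.9-fold higher. Solyc06g065970 stood at 1953 RPKM in MoneyMaker leaf and was listed at 0 in both LA0722 libraries, at least 74.6-fold lower in LA0722 leaf. Solyc01g090970 went from 3791 RPKM in MoneyMaker leaf to 9.01 RPKM in LA0722 leaf, a single read, a 421-fold difference with an interval of 75.2 to 16656. The median difference over the genes compared was 0.60 as deposited. Median-ratio size factors shifted LA0722 leaf by -0.70 log2 units against MoneyMaker leaf and left 726 genes higher and 1889 lower, so the share of higher genes went from 53.0% to 27.8%. It was 43.2% with upper-quartile scaling and 48.9% with equal sums, so the direction of the majority turned under all 3, as it did with a pseudocount of 20 RPKM (419 higher and 435 lower) and with no minimum level (1421 and 1480).

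Ripe fruit was compared between the same 2 species. In LA0722 ripe fruit 644 genes were higher and 998 lower among 7088 compared, against means of 121.1 and 140.6 from counting error alone. Solyc02g086310 was listed at 0 in MoneyMaker ripe and breaker fruit, stood at 253 RPKM in mature green and at 5466 RPKM in LA0722 ripe fruit (329 reads), at least 140-fold higher than in MoneyMaker ripe fruit. Solyc06g048840 was listed at 0 in MoneyMaker ripe fruit and stood at 1931 RPKM in LA0722, at least 49.1-fold higher. Solyc05g014300 stood at 1024 RPKM in MoneyMaker ripe fruit and Solyc09g009650 at 870 RPKM. Both were listed at 0 in LA0722 ripe fruit, at least 14.1-fold and 6.2-fold lower. They held 54 and 24 reads in MoneyMaker ripe fruit, on inferred coding lengths of 195 and 102 nt. Solyc09g009650 was present in all 7 MoneyMaker libraries and listed at 0 in both LA0722 libraries. Solyc10g080210, the gene with the largest increase from mature green to ripe in MoneyMaker, stood at 17185 RPKM in LA0722 ripe fruit and at 12830 RPKM in MoneyMaker ripe fruit. As deposited, 39.2% of the genes past the rule were higher in LA0722; with median-ratio size factors, which shift LA0722 ripe fruit by 0.57 log2 units, the figure was 61.1%, with 872 higher and 555 lower, and it was 49.6% with equal sums (shift 0.28).

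The contrast of ripe fruit with leaf was then set side by side in both species, each from its own libraries. In MoneyMaker 2008 genes were higher and 1416 lower in ripe fruit than in leaf among 7616 compared, and in LA0722 1458 were higher and 1463 lower among 7551. Among the 5657 genes compared in both, 590 were higher in ripe fruit in both species where independent lists would share 271.9, and 539 were lower in both where independent lists would share 126.8; their order turned with median-ratio size factors (376 and 756), upper-quartile scaling (526 and 626), equal sums (536 and 606) and no minimum level (665 and 710). Opposite directions were less frequent than for independent lists, with 74 genes higher in MoneyMaker and lower in LA0722 ripe fruit (268.1 for independent lists) and 18 the other way (128.6). Across these genes the differences correlated at 0.68 (Pearson) and 0.56 (Spearman), and 68.7% had the same sign. Solyc07g049140 led the fruit side in both species, with 0 in both leaves, at least 3818-fold and 4473-fold above the leaf floors. Solyc10g017970 in MoneyMaker (39761 RPKM) and Solyc10g017980 in LA0722 (66929 RPKM) came next and were listed at 0 in both leaf libraries. Their inferred coding lengths were 183 and 192 nt. Solyc02g085950 led the leaf side in MoneyMaker, with 36183 RPKM in leaf and 0 in ripe fruit, and Solyc12g099650 in LA0722, with 7191 RPKM and 0. In MoneyMaker the split depended on scaling, with 58.6% of genes past the rule higher in ripe fruit as deposited and 24.8% with median-ratio size factors (shift -1.28), 46.5% with upper-quartile scaling and 48.6% with equal sums, while in LA0722 it was 49.9% as deposited and 49.6%, 50.6% and 51% under these scalings, the last 2 of which turned the majority.

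**Figure D3:**
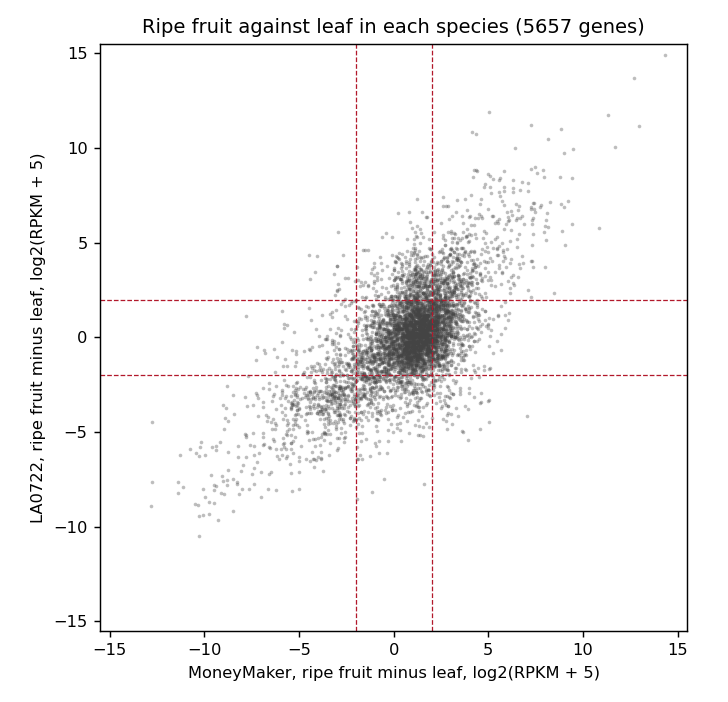
Difference between ripe fruit and leaf in log2(RPKM + 5) for each of 5657 genes at 25 RPKM or more in at least 1 library of each species, MoneyMaker on the x axis and LA0722 on the y axis; dashed lines mark the rule of size of 2 log2 units. Most genes past the rule in both species lie in the same direction, 590 in the upper right and 539 in the lower left.

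Genes that differed during ripening in MoneyMaker were followed in LA0722, whose libraries had no part in choosing them. Of the 689 genes higher in ripe than in mature green MoneyMaker fruit, 461 reached 25 RPKM in LA0722 leaf or ripe fruit, and of these 273 were higher and 43 lower in LA0722 ripe fruit than in LA0722 leaf, with a median difference of 2.88 (random lists -0.21 to 0.23). Together the 689 genes took 24.6% of summed RPKM in MoneyMaker ripe fruit, 26.7% in LA0722 ripe fruit and 2.5% in LA0722 leaf. Of the 1228 genes lower in ripe than in mature green fruit, 581 reached the level in LA0722, with 313 lower and 75 higher in LA0722 ripe fruit than in leaf and a median of -2.20 (random lists -0.25 to 0.20). They took 28.2% of summed RPKM in LA0722 leaf and 3.7% in LA0722 ripe fruit. Both medians kept their sign and varied in size with the cut: for the genes higher and lower in MoneyMaker they were 0.74 and -0.33 with no minimum level, 1.16 and -1.16 with a rule of 1 log2 unit, and 4.51 and -3.21 with a level of 100 RPKM. No LA0722 fruit before ripeness was among the libraries, so the comparison is of ripe fruit with leaf and not of ripening stages. The random lists were matched on mean expression only. All 689 genes stood at 25 RPKM or more in MoneyMaker ripe fruit and 185 in MoneyMaker leaf, against 111 and 586 of the 1228. Since the contrast of ripe fruit with leaf was largely shared by the species, these medians cannot separate ripening from that contrast.

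The differences between species were compared across both tissues. Among the 4593 genes compared in both, 131 were lower in LA0722 in leaf and in ripe fruit, where independent lists would share 50.2, and 60 were higher in both, where independent lists would share 41.0. Keeping only genes whose exact interval on recovered reads excluded no change left 72 lower and 47 higher in both. LA0722 reads assigned less often to the gene models would also lower genes in both tissues and cannot be told apart here. Across genes the species differences in leaf and in ripe fruit correlated weakly, at 0.20 (Pearson) and 0.20 (Spearman). The contrast of ripe fruit with leaf was larger in LA0722 by at least 3 log2 units for 787 genes and smaller for 1010 of the 9510 genes at 25 RPKM or more in any of the 4 libraries. Solyc02g086310, with 5466 RPKM in LA0722 ripe fruit and 0 in the other 3 libraries, and Solyc10g078770, with 833 RPKM there, led the first group. Solyc02g085320, with 651 RPKM in MoneyMaker ripe fruit, 0 in LA0722 ripe fruit and 83.6 RPKM (4 reads) in LA0722 leaf, and Solyc01g087020 led the second. Under median-ratio size factors these counts were 1441 and 479, so which group was larger turned, as it did with upper-quartile scaling (1016 and 836) and equal sums (964 and 842). Likewise 375 genes were higher and 357 lower in both tissues with a rule of 1 log2 unit, against 60 and 131.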

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

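The contrast below was planned; with 1 library per group there was no test of the difference between the tissues.

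The rule of size was met in opposite directions in leaf and ripe fruit by 114 of 4593 genes, a difference between tissues that was not tested; independent lists would give 115.3 such genes, so the total was no larger than without any relation between the tissues. Of these, 78 were higher in LA0722 leaf and lower in LA0722 ripe fruit, where independent lists would share 93.2, and 36 went the other way, where independent lists would share 22.1.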

How the results depend on the processing

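The counts below are counts of genes past a rule of size. Among the planned counts that were recomputed under a setting, those not listed stayed within 1.5 times of the reported count. The interval on recovered reads was not run for the difference of contrasts, and the numbers of genes at 25 RPKM were recomputed only at 10 RPKM and above 0. The cause of each move was not tested, except that a stricter level, a larger pseudocount or the looser rule of size of 1 log2 unit passes other numbers of genes by construction. No paired analysis was possible because each group has 1 library and the groups share fewer than 2 replicate numbers; a fit of tissue with species as a block on the 4 leaf and ripe fruit libraries was not run, and its only measure of spread would be the difference of contrasts itself. The alternatives planned for gene lists were not run, because no table paired the IDs with names. Equal sums without the 10 most abundant genes moved no planned count by over 1.5 times. Depth limits all results, since 3 reads on 1 kb were worth between 7.89 and 14.2 RPKM.

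With a pseudocount of 20 RPKM, predominant genes numbered 271 in root, 29 in stem, 189 in leaf, 47 in mature green, 42 in breaker and 46 in ripe fruit, and 454 for fruit as 1 organ. Higher and lower genes numbered 343 and 328 from mature green to breaker, 176 and 206 from breaker to ripe, 357 and 456 from mature green to ripe, 419 and 435 for leaf between species (turning the majority, as from mature green to breaker), and 253 and 454 for ripe fruit between species. In both tissues 16 genes were higher, 35 lower and 27 opposite, and the tissue contrast was larger in LA0722 for 204 and smaller for 330. With a pseudocount of 1 RPKM the last counts were 1336 and 1599. With a level of 100 RPKM, predominant genes numbered 244 in root, 45 in stem, 49 in mature green, 46 in breaker and 45 in ripe fruit, and 492 for fruit as 1 organ. Higher and lower genes numbered 347 and 290 (majority turned), 179 and 188, and 367 and 388 for the ripening comparisons in the same order, 488 and 369 for leaf and 215 and 452 for ripe fruit between species. In both tissues 14 were higher, 35 lower and 30 opposite, and the contrast was larger for 361 and smaller for 495. With no minimum level 202 were lower in both tissues and 183 opposite.

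With median-ratio size factors, predominant genes numbered 53 in stem, 630 in leaf, 1328 in flower, 48 in ripe fruit and 513 for fruit as 1 organ. Under that scaling 276 genes were higher from breaker to ripe, 726 higher and 1889 lower for leaf between species and 555 lower for ripe fruit between species, and the tissue contrast was larger for 1441 and smaller for 479. Upper-quartile scaling gave 59 stem-, 458 leaf- and 1212 flower-predominant genes, and 593 genes lower from mature green to breaker. Keeping only genes whose exact interval on recovered reads excluded no change left 52 breaker- and 57 ripe-predominant genes, 303 higher and 402 lower from breaker to ripe, and 72 lower in both tissues and 67 opposite. With a rule of 1 log2 unit, predominant genes numbered 1044 in root, above 979 in flower, 371 in stem, 644 in leaf, 346 in mature green, 308 in breaker and 400 in ripe fruit, and 2213 for fruit as 1 organ. Higher and lower genes numbered 1478 and 2152, 1529 and 1478 (majority turned), and 1688 and 2286 for the ripening comparisons, 2794 and 1720 for leaf and 1481 and 2138 for ripe fruit between species. In both tissues 375 were higher, 357 lower and 534 opposite, and with 2 log2 units the contrast was larger for 1471 and smaller for 2186.

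Genes above 10 RPKM numbered 11699 in root, 10672 in stem, 8428 in MoneyMaker leaf, 6055 in flower, 10947 in mature green, 9337 in breaker and 8866 in MoneyMaker ripe fruit, 8711 in LA0722 leaf and 8373 in LA0722 ripe fruit. Genes above 0 numbered 17598, 16480, 15283, 10948, 16151, 13664, 13123, 13475 and 12234 in the same order. With a pseudocount of 1 RPKM the Pearson correlation across genes was 0.86 for breaker with ripe fruit, 0.76 for leaf and 0.82 for ripe fruit between species, and 0.51 for MoneyMaker leaf with flower. Among the analyses chosen after seeing the data, 4 medians changed sign. The root set from breaker to ripe had a median of -0.18 with a pseudocount of 20 RPKM and -0.56 with median-ratio size factors, and the flower set from mature green to ripe had 0.11 with a level of 100 RPKM and 0.50 with upper-quartile scaling. A further 55 values of those analyses moved in size and 107 did not.

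Higher and lower genes of ripe fruit against leaf numbered 992 and 724 in MoneyMaker and 712 and 675 in LA0722 with a pseudocount of 20 RPKM, with 318 higher and 282 lower in both species. With a level of 100 RPKM they numbered 1041 and 582, 616 and 596, and 301 and 246 in both; in LA0722 both settings turned the majority. Median-ratio size factors gave 841 and 2554 in MoneyMaker and 376 higher in both species. With a rule of 1 log2 unit 3768 were higher in MoneyMaker, 2416 higher and 2428 lower in LA0722, and 1319 higher and 839 lower in both. Medians of organ sets with no minimum level were 0.0 at every step for the root, stem and flower sets, and 0.0, 0.0 and -0.16 for the leaf set from mature green to breaker, breaker to ripe and mature green to ripe. With a level of 100 RPKM the root set had 2.14 from mature green to breaker and 1.76 to ripe, the leaf set -3.44 from mature green to ripe and the flower set 1.18 from mature green to breaker. Under a rule of 1 log2 unit the stem set had -0.26 from breaker to ripe and -0.92 from mature green to ripe, and the leaf set -0.27, -0.50 and -1.04 over the 3 comparisons. The genes that were lower in ripe MoneyMaker fruit had a median of -1.56 in LA0722 with a pseudocount of 20 RPKM. Those that were higher had 3.26 with median-ratio size factors and 2.38 with upper-quartile scaling. The root set had 1.70 with median-ratio and 2.19 with upper-quartile scaling from mature green to breaker, and the leaf set -0.14 and -0.04.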

Other observations

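The tests on genes unseen in LA0722, and the bound on fewer reads as the whole cause and the Poisson limit for the flower pattern, were chosen after their results had been seen; the other tests were set before their own values were computed, though neighbouring IDs among the leading genes and the gene counts of the libraries had been noticed.

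Genes predominant in the same organ often had neighbouring IDs. With IDs taken to follow position along a chromosome, which was not checked against a genome here, 200 adjacent pairs among the 2565 organ-predominant genes shared their organ, against a mean of 62.4 and a highest value of 91 in 1000 random placements. Root had 67 such pairs (mean 11.7, highest 25), flower 59 (22 and 37), fruit 59 (24.9 and 40), leaf 12 (3.4 and 11) and stem 3 (0.4 and 3). The longest run held 6 flower-predominant genes, from Solyc06g008630 to Solyc06g008680, and the next held 5 leaf-predominant genes, from Solyc02g070970 to Solyc02g071010, and 5 root-predominant genes, from Solyc07g009060 to Solyc07g009100. These runs were picked after their lengths were seen.

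The 200 pairs lie above every random placement, which argues against chance. Recovered coding lengths differed by more than 10% in 143 pairs, against a highest random value of 81. That cannot decide whether reads were shared between copies of about equal length. The lengths are the smallest that fit and can be a fraction of the true ones for genes listed in few libraries. A gene annotated as 2 neighbouring models cannot be told apart from neighbours that are expressed together: the reads of 59.0% of 161 pairs were in a constant ratio over the libraries (chi-square p above 0.05), between the bounds set, and pairs with few reads can pass that test whatever their ratio. A candidate explanation is tandem gene copies expressed in the same organ, a hypothesis that was not tested, since no sequences were used here.

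More genes were seen in MoneyMaker and not in LA0722 than the reverse. Of 2962 genes at 25 RPKM or more in both MoneyMaker leaf and ripe fruit, 57 were at 0 in both LA0722 libraries, and the reverse held for 11 of 3332. Counting error at equal expression predicted 2.78 genes in place of the 57, with an upper limit of 6, which argues against it as their cause. For the reverse it predicted 0.64 genes, so counting error leans the same way. Whether it accounts for the imbalance between 57 and 11 was not tested. LA0722 reads assigned less often to the gene models stay open and cannot be told apart from real differences between the species: the ratio at 100 RPKM or more was 2.5, from 5 genes against 2, but the median species difference was 0.60 in leaf and -0.22 in ripe fruit and moves with the scaling. Of 1350 genes at 25 RPKM or more in all 7 MoneyMaker libraries, 11 were at 0 in both LA0722 libraries, where independence would give 1.3.

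Flower listed the fewest genes, 89.5% as many as LA0722 ripe fruit, the lowest other library, and 90.1% at a common 204210 recovered reads, with an upper bound of 92.4% from the Poisson spread of both numbers; this argues against fewer reads as the whole cause. By the implied totals flower was not the shallower of these libraries (213741 against 211200 reads), so depth then accounts for none of this gap, and a small part stays open only by the recovered reads, which are lower bounds. Of 1717 genes at 25 RPKM or more in all 8 other libraries, 86 were at 0 in flower, against 64.6 (Poisson upper limit 81) if all kept their proportions at 0.24 of their usual level, a ratio of 1.3. Because 0.24 was taken from the same genes, dilution by abundant flower transcripts cannot be told apart from other causes that lower these genes. Uneven amplification of the cDNA was not tested.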
